A study of Mus musculus with 6 samples.

How the data were processed

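Bulk RNA sequencing had been done on fibroblasts isolated from the enthesis, the site where tendon or ligament joins bone, of SKG mice. SKG mice carry a mutation of Zap70 and are prone to autoimmune arthritis. The labels put 3 samples in a diseased and 3 in an un-diseased group and number the samples of each group 1 to 3. The titles of the diseased samples carry NTS and those of the un-diseased ones UN, which the labels do not explain, so the groups rest on the treatment label alone. The labels do not say whether the samples of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. Per the labels, RNA was extracted with TRIzol and read in pairs on a BGISEQ-500.

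The deposited table held 17419 genes with estimated counts per sample, made by the authors. Per the submitters' processing notes, HISAT2 2.0.4, RSEM 1.3.1 and DESeq2 1.4.5 were used with the mouse build GRCm38, and the notes give no role or order. Of the estimated counts, 9.6% were not whole, and all were rounded to whole numbers before any test. The authors' deposited table also gave a log2 ratio of un-diseased over diseased and a p-value and q-value per gene, which served only for comparison. Total counts per sample lay between 16720605 and 18290870. A count of 3, the limit that a count of 0 allows, was worth 0.147 to 0.188 CPM (counts divided by the TMM-scaled library total, on the usual CPM scale), for counting error only. The 20 genes with most counts took 18.1% to 23.1% of a sample. Gene numbers were matched to the RefSeq table of GRCm38, which held 17372 of the 17419, and positions are from that table and 1-based.

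Genes were kept with filterByExpr of edgeR 4.0.16 (R 4.3.3) at its least count of 10, which left 13264 genes. Libraries were scaled with TMM, and diseased was compared with un-diseased by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 fold change is diseased minus un-diseased, with its standard error (SE), and group values are mean CPM ± SD over 3 samples. Before the data were examined, 35 gene lists with 695 entries were written, of which 681 entries were in the table. The 31 lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. The named genes were also fixed then: Sdc1 and Sox5; the 8 largest rises and 8 largest falls past the threshold with a mean log2 CPM of at least 2 and no overlap between the groups, leaving out unnamed gene models and immune receptor segments; and up to 3 called members of each list with the smallest adjusted p, or, where none was called, the member with the highest mean CPM, as a value.

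Samples that share a number deviated together from their group means. Over the 13264 genes the correlation of deviations was 0.487 for replicate 1, 0.578 for replicate 2 and 0.276 for replicate 3, and each sample correlated best with its own number, so the numbers were taken to pair the samples. The pairing comes from the replicate numbers in the labels and these correlations. The comparison with the replicate number as a block was an alternative and is given where it changed a call or moved a count by more than 1.5 times. Pairs of samples of one group differed by far more than sampling noise, with a chi-square per gene of 24.2 to 58.5, so no 2 samples were taken to be the same library; this does not show that they came from separate animals or cultures.

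The other alternatives were size factors of the RLE kind, upper-quartile factors, 2 other filters, DESeq2 1.42.0, limma-voom, a threshold of 0.01, an estimated correlation and fry for the lists, and leaving out each sample. The steps were tested on simulated data. Changed genes were drawn only from genes at a higher mean log2 CPM than the 2 required of the largest changes. Recovery at lower levels was therefore not tested. Dispersions came from the blocked design in both simulations, with and without pair effects. With 200 of 13264 genes changed and the pair effects of these samples, the unblocked edgeR test recovered 61% of the 2-fold and 97% of the 4-fold changes with 0 false calls; at the same 2 sizes the blocked test recovered 100% and 100%, with 6.1% of its calls false. DESeq2 without the block recovered 86% and 98% there, with 0 false calls. Simulated without pair effects, the unblocked edgeR and DESeq2 tests recovered 100% at both sizes, with 7% and 9.9% of their calls false, and 6.1% were false with the block in either tool. The raised list, that of collagen, passed camera in both simulations with and without the block. Another list passed too, 1 in each fit without pair effects and 0 with them. Counts were drawn independently for each gene, so beyond the pair effects list members were uncorrelated. In the data the estimated correlation of the collagen list was 0.56, and 0.49 with the block. The simulation thus does not test the preset correlation of 0.01.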

Results

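RNA abundance was measured in 6 samples of entheseal fibroblasts, 3 labelled diseased and 3 labelled un-diseased. Total counts were 18241669, 17233405 and 18290870 in diseased replicates 1, 2 and 3, and 17864659, 16720605 and 17580921 in the un-diseased ones. The comparison asks how the transcriptome of entheseal fibroblasts differs between diseased and un-diseased SKG mice; the title of the series names syndecan-1 (Sdc1) and the transcription factor Sox5 together with mechanical strain.

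Smoc1, Tnn and Spp1 were higher in diseased samples, and Igf2, Col6a5 and Mrgprg were lower. Macrophage markers were also higher in these bulk samples (median log2 fold change 1.34), so no change was assigned to a cell type. Smoc1, a secreted calcium-binding matrix protein, rose from 14.1 ± 2.46 to 67.4 ± 10.1 CPM (SD, n = 3 in each group), and Tnn, the matrix glycoprotein tenascin-N, from 282.6 ± 101.7 to 906.2 ± 120.4 CPM. Spp1, which encodes osteopontin, rose from 152.3 ± 42.9 to 459.1 ± 78.2 CPM. Igf2, a growth factor, fell from 140.6 ± 31.8 to 26.7 ± 6.17 CPM, and Col6a5, a collagen VI chain, from 262 ± 139 to 34.2 ± 16.3 CPM. By edgeR's quasi-likelihood test 213 genes were higher and 282 lower in diseased samples among 13264 tested, and 217 of these changed at least 2-fold, 82 upward and 135 downward. The groups did not overlap for 31.9% of tested genes, where chance gives 10% if the 6 samples are exchangeable, which samples paired by number are not.

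With the replicate block, 1397 genes were higher and 1770 lower, and 808 changed at least 2-fold, 385 upward and 423 downward. The blocked calls were 3167 of the 13264 tested genes, against 495 without the block. Blocked counts of list members below are to be read against that background. All 495 genes called without the block were called with it in the same direction. Upper-quartile scaling gave 417 higher and 288 lower, so that 59.1% of calls were upward against 43% with TMM, and 130 upward and 128 downward at 2-fold. A macrophage score per sample, the mean log2 CPM of 18 macrophage markers centred within its group, was a covariate chosen after seeing the data. With it 261 genes were higher and 225 lower, or 53.7% upward, with 176 upward and 121 downward at 2-fold. The excess of falls thus held under neither upper-quartile scaling nor this covariate. Centred so, the score leaves the difference between groups in macrophage markers unadjusted. Single samples decided how many genes passed: 2 were higher and 3 lower without diseased replicate 3, 3 and 7 without un-diseased replicate 2, 14 and 23 without un-diseased replicate 3, 39 and 46 without diseased replicate 1, 36 and 87 without diseased replicate 2, and 354 and 721 without un-diseased replicate 1. In the authors' deposited table, a q-value below 0.05 was given to 1361 genes, 574 higher and 787 lower in diseased, and 494 of the 495 edgeR calls were among them in the same direction.

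Sdc1 (gene 20969, GRCm38 chromosome 12, 8771396 to 8793716) encodes a cell-surface heparan sulfate proteoglycan and had 206 ± 28.2 CPM in diseased and 139 ± 36.1 in un-diseased samples (SD, n = 3 each). Its log2 fold change was 0.57 (SE 0.20) with an adjusted p of 0.13 by edgeR, which did not pass. Its unadjusted p by edgeR was 0.0235, and adjusted over the list of the 2 title genes alone it passed. With the replicate block the change was 0.59 (SE 0.12) with an adjusted p of 0.0106, which passed. Sox5 (gene 20678, chromosome 6, 143828425 to 144782287) had 66.7 ± 10.6 CPM in diseased and 57.7 ± 11.6 in un-diseased samples, a log2 fold change of 0.21 (SE 0.17) with an adjusted p of 0.445 by edgeR. The authors' deposited table gives log2 ratios of un-diseased over diseased of -0.56 with a q-value of 0.0917 for Sdc1, and -0.20 with a q-value of 0.657 for Sox5.

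**Figure D1:**
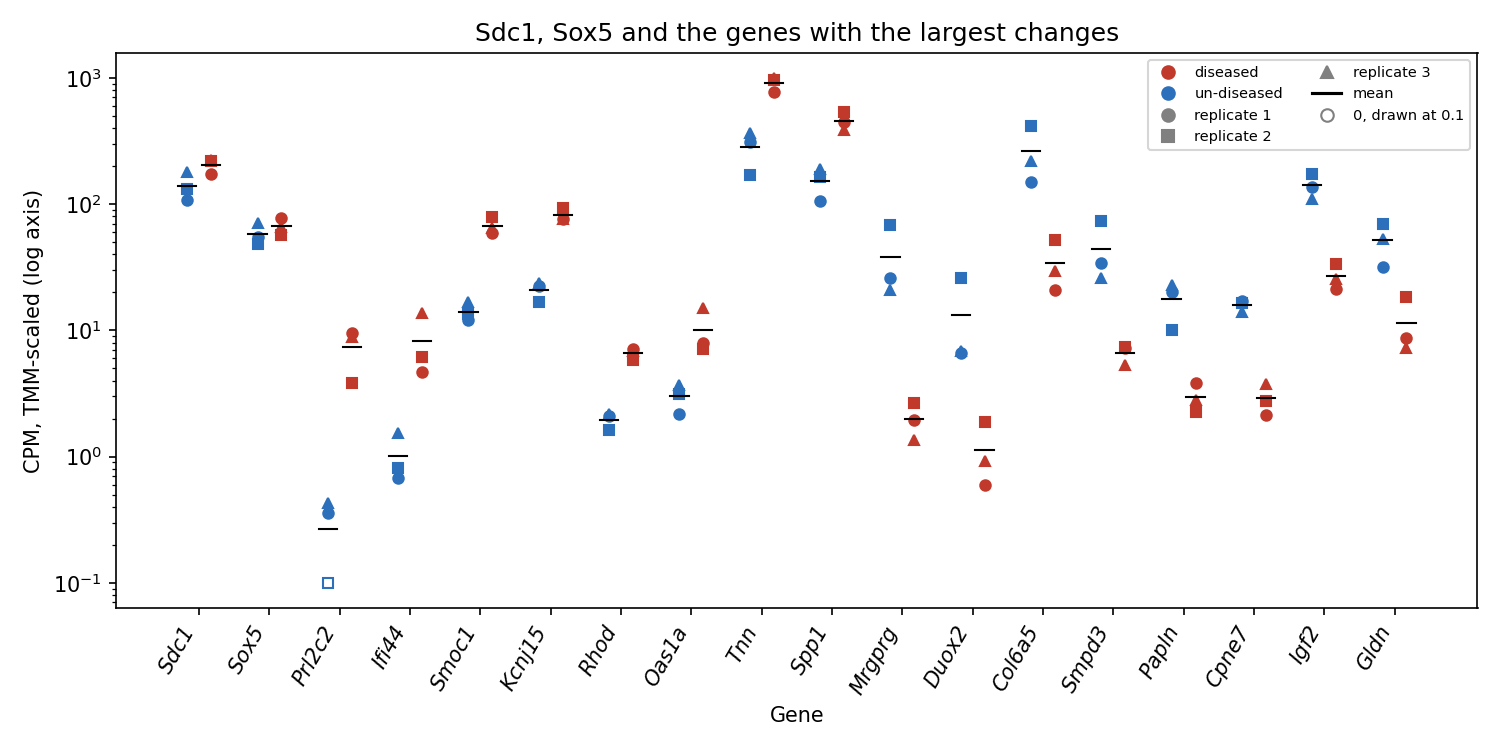
CPM on a log axis for Sdc1, Sox5 and 16 genes, the 8 largest rises and 8 largest falls that passed with a mean log2 CPM of at least 2 and no overlap between groups; each point is a sample, marked by group colour and replicate shape, and lines are group means. The 3 diseased samples of each of the 16 genes lie all above or all below the 3 un-diseased ones, as for Smoc1 with means of 67.4 and 14.1 CPM.

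The other rises of the 16 genes were Prl2c2 (log2 fold change 4.74, SE 0.68), Ifi44 (3.02, SE 0.51), the potassium channel gene Kcnj15 (1.97, SE 0.16), Rhod (1.74, SE 0.21) and Oas1a (1.74, SE 0.34). Prl2c2 had 0.266 ± 0.233 CPM in un-diseased samples, 1 of them at 0, and belongs to a family of near-identical prolactin genes, as Oas1a does to the Oas genes, so its counts and those of Oas1a are uncertain where reads were shared between copies. Smoc1 lies on chromosome 12 from 81026808 to 81186414 and changed by 2.26 (SE 0.17, adjusted p = 0.00642 by edgeR). The largest of the 8 falls was that of Mrgprg, a receptor gene of the Mas-related family on chromosome 7 from 143763710 to 143766993, at -4.27 (SE 0.53, adjusted p = 0.0247 by edgeR). Its CPM was 38.4 ± 26.1 in un-diseased and 1.99 ± 0.665 in diseased samples. Un-diseased replicates 1, 2 and 3 had 26.06, 68.31 and 20.76 CPM, so the size of the fall, not its direction, rests in part on replicate 2. Duox2 (-3.58), Col6a5 (-2.94), Smpd3 (-2.75), Papln (-2.56), Cpne7 (-2.46), Igf2 (-2.40) and Gldn (-2.18) were the other 7 of these falls. Duox2 had 6.67, 26.05 and 6.88 CPM in un-diseased replicates 1, 2 and 3, so the size of its fall rests in part on replicate 2. The same holds for Smpd3, with 33.88, 72.94 and 26.21 CPM, and Col6a5, with 150.73, 417.44 and 217.75. In diseased replicates 1, 2 and 3 Ifi44 had 4.65, 6.1 and 13.81 CPM and Oas1a 7.92, 7.1 and 15.05. The sizes of these 2 rises rest in part on diseased replicate 3. With limma-voom the adjusted p was 0.0542 for Ifi44, 0.0559 for Oas1a and 0.0761 for Duox2, which did not pass.

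Genes of fibrillar collagen and crosslinking were higher as a group: 4 of 23 tested members rose, 0 fell and 19 did not pass, with a median log2 fold change of 0.49 (camera adjusted p = 1.9e-05; adjusted p = 0.932 with an estimated correlation). There, 10 rose and 1 fell adjusted over the list alone, and with the replicate block 9 rose and 1 fell over all genes. Col12a1 went from 467.1 ± 102.6 to 1098 ± 263 CPM, the collagen chaperone Serpinh1 from 579 ± 96.8 to 1204 ± 144 CPM, and P4ha3, a collagen prolyl hydroxylase, from 108 ± 7.37 to 192.1 ± 25.2 CPM. In the contractile myofibroblast list 4 of 18 members rose and 0 fell (median 0.44; camera adjusted p = 0.00872; adjusted p = 0.932 with an estimated correlation). The risen members included Acta2, smooth muscle actin, with 29.4 ± 6.23 against 13.7 ± 2.13 CPM, Tpm2 with 36.6 ± 4.42 against 15.8 ± 1.42, and Cnn2 with 31.9 ± 5.84 against 15.5 ± 1.22. In this list 7 rose and 0 fell adjusted over the list alone, and with the block 8 rose and 1 fell. The call was lost without diseased replicate 2 and without un-diseased replicate 1, with adjusted p up to 0.112. With the replicate block it was also lost after a GC and length correction (adjusted p = 0.0573) and without pair 1 (0.0934) or pair 2 (0.169).

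In the tendon and enthesis list 3 of 20 members rose and 1 fell, and the list did not pass (camera adjusted p = 0.0711). It passed as higher without diseased replicate 3 (adjusted p = 0.0348), without un-diseased replicate 2 (0.0322), with no filter beyond 1 count (0.0317) and with the block without pair 3 (0.0469). Thbs4 rose from 1895 ± 340 to 4227 ± 805 CPM and Cilp from 747.9 ± 60 to 1405 ± 63.4, while Gli1, a hedgehog pathway transcription factor, fell from 18.9 ± 1.98 to 7.42 ± 0.925. Of these members, 8 rose and 2 fell adjusted over the list alone, and with the block 8 rose and 1 fell. Bone formation genes went both ways, 2 rising and 3 falling among 17 (camera adjusted p = 0.821): Spp1 rose, and Alpl, alkaline phosphatase, fell from 19.5 ± 1.39 to 7.29 ± 0.702 CPM, as did Smpd3. Of them 3 rose and 3 fell adjusted over the list alone, and 4 rose and 3 fell with the block. Among 23 BMP signalling genes 0 rose and 2 fell, the median being -0.48 (camera adjusted p = 0.00872; adjusted p = 0.932 with an estimated correlation). Bmp4 fell from 18.1 ± 4.49 to 7.84 ± 0.402 CPM and Gdf10 from 143.2 ± 11.3 to 81.8 ± 9.75. For BMP genes, 0 rose and 7 fell adjusted over the list alone, and 0 rose and 12 fell with the block.

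Of the mechanical lists, 2 of 21 YAP and TEAD targets rose and 1 fell (camera adjusted p = 0.688), with Nt5e and Amotl2 higher at log2 fold changes of 0.96 and 0.63 and Igfbp3 lower at -1.77. The targets had 4 rises and 5 falls adjusted over the list alone, and with the block 4 rose and 6 fell. Among 20 mechanosensing channels and adhesion genes 0 rose and 2 fell, Itga2 at -1.35 and Pxn at -0.80 (camera adjusted p = 0.802); 0 rose and 2 fell adjusted over the list alone, and 1 rose and 3 fell with the block. The median and the mean of both lists differed in sign, 0.03 and -0.17 for the targets and 0.06 and -0.12 for the channels.

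The inflammatory lists differed in direction. Of 22 IL-17 and NF-kB response genes 1 rose and 2 fell, with a median of -0.58 (camera adjusted p = 0.011; adjusted p = 0.932 with an estimated correlation); Irak3 fell from 258.5 ± 66.3 to 104.8 ± 30.1 CPM and Cebpd from 221.1 ± 17.8 to 126.3 ± 26.8, whereas Saa3, an acute-phase protein gene, rose from 247.7 ± 46.8 to 614.1 ± 219.8. Among them 2 rose and 6 fell adjusted over the list alone, and with the block 1 rose and 15 fell. Without diseased replicate 1 the list's adjusted p was 0.0513. Of 30 cytokines and chemokines only Ccl11 passed, over all genes and adjusted over the list alone, falling from 149.8 ± 56.9 to 50.4 ± 7.2 CPM; the list had an adjusted p of 0.311 and, with the replicate block, 0.0265 (4 rose and 14 fell; adjusted p = 0.704 with the block and an estimated correlation). The blocked call was lost without pair 1 (adjusted p = 0.132).

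Interferon response genes were higher: 3 of 28 rose and 0 fell, Ifi44, Oas2 and Oas1a, with a median of 0.38 (camera adjusted p = 0.00872; adjusted p = 0.932 with an estimated correlation). Of the list, 6 rose and 0 fell adjusted over the list alone, and with the block 7 rose and 1 fell. The call was lost without diseased replicate 3 and without un-diseased replicate 1, with adjusted p up to 0.131, and with the block without pair 3 (adjusted p = 0.301). All 21 antigen presentation genes had a positive fold change (median 0.77; camera adjusted p = 1.9e-05; adjusted p = 0.932 with an estimated correlation). Of these, 0 passed singly by edgeR, 16 had an unadjusted p under 0.05, and DESeq2 called 11; adjusted over the list alone 12 rose, and with the block 14 rose. H2-D1, a class I histocompatibility gene with near-identical relatives, had 1666 ± 457 CPM in diseased and 1073 ± 79.3 in un-diseased samples. Macrophages express class II antigen presentation genes, which are only part of this list, and the median of their markers was 1.34 in the same comparison. H2-D1 had 2168 CPM in diseased replicate 3 against 1554 and 1275 in diseased replicates 1 and 2. Diseased replicate 3 had the lowest mean log2 CPM of macrophage markers in its group, 2.44. Within pairs 1, 2 and 3, however, the antigen presentation list had medians of 0.47, 0.45 and 1.2. The macrophage list had 1.55, 0.96 and 2.4, so both differences were largest in pair 3. Whether the antigen presentation list follows macrophage RNA was not tested.

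Markers of other cells differed as well. All 18 tested macrophage and monocyte markers had a positive fold change, with a median of 1.34 (camera adjusted p = 0.000113; adjusted p = 0.932 with an estimated correlation). Of these, 0 passed singly by edgeR, 8 had an unadjusted p under 0.05 and DESeq2 called 4; adjusted over the list alone 0 rose, and with the replicate block 18 of 18 rose. Lyz2, lysozyme, had 144 ± 53 CPM in diseased and 43.8 ± 37.1 in un-diseased samples, with an adjusted p of 0.165 by edgeR and 0.00574 with the block. Neutrophil markers had an adjusted p of 0.278 and, with the replicate block, 0.0426 (4 of 12 rose; adjusted p = 0.891 with the block and an estimated correlation). The blocked call was lost after the GC and length correction (adjusted p = 0.0588) and without pair 1 (0.148) or pair 3 (0.11) and held without pair 2 (3.43e-06), and without the block the list passed without diseased replicate 3 (0.0348), without un-diseased replicate 2 (0.00064) and with the macrophage covariate (0.00781). S100a9 had 36.6 ± 25 CPM in diseased and 23.8 ± 31.5 in un-diseased samples, with an adjusted p of 0.706 by edgeR and 0.0449 with the block. Among 9 adipocyte genes 0 rose and 2 fell, Plin4 at -1.37 and Pnpla2 at -0.67 (camera adjusted p = 0.00178; adjusted p = 0.932 with an estimated correlation), and 6 fell both adjusted over the list alone and with the block. Of 6 epithelial genes 1 fell, Perp at -1.58 from 2.75 ± 0.641 CPM (camera adjusted p = 0.0406; adjusted p = 0.932 with an estimated correlation), and 3 fell both adjusted over the list alone and with the block. Both of these list calls were lost without un-diseased replicate 1, with adjusted p of 0.0521 and 0.102, and the epithelial one also with the block without pair 1 (0.0934) or pair 2 (0.0548).

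**Figure D2:**
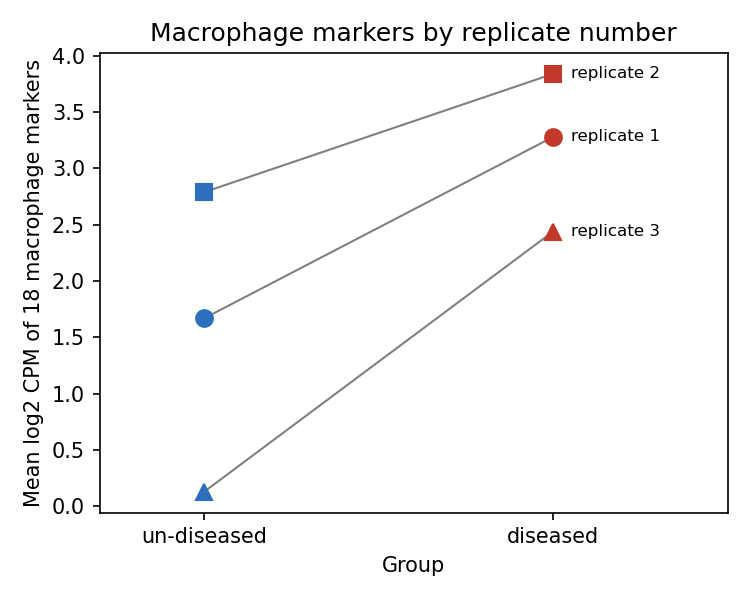
Mean log2 CPM of 18 macrophage markers in each sample, un-diseased on the left and diseased on the right, with lines joining samples of one replicate number. The mean was higher in the diseased sample of each number, 3.28 against 1.67, 3.84 against 2.79 and 2.44 against 0.13.

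Cell cycle genes were higher with small changes: 2 of 30 rose, Mcm2 and Mcm5, replication licensing genes, at 0.88 and 0.77, and 0 fell (median 0.55; camera adjusted p = 8.18e-05; adjusted p = 0.932 with an estimated correlation). Here 3 rose adjusted over the list alone, and with the block 11 rose and 1 fell. The adventitial and universal fibroblast list had 1 rise, Cd248 at 0.60, and 1 fall, Gfpt2 at -1.61 (camera adjusted p = 0.075); 3 rose and 6 fell both adjusted over the list alone and with the block. This list passed as lower without diseased replicate 3 (adjusted p = 0.0399), without un-diseased replicate 3 (0.0293), with the macrophage covariate (0.0404) and with the block without pair 3 (0.0169). C7 of the complement list fell from 87.5 ± 3.73 to 30.3 ± 6.63 CPM, Timp3 of the matrix enzyme and inhibitor list fell at -1.14, and Wnt2 and Wnt11 of the Wnt list fell at -1.66 and -1.01 (camera adjusted p = 0.821, 0.421 and 0.688 for these lists). In the unfolded protein response list Pdia4 rose at 0.80 while Trib3 and Herpud1 fell at -1.45 and -0.53 (camera adjusted p = 0.688), and in the hypoxia and glycolysis list Pfkl rose at 0.48 and Egln3 fell at -1.77 (camera adjusted p = 0.532). Single members rose in the endothelial (Erg, 1.43), pericyte (Rgs4, 1.09) and Schwann cell lists (Ncam1, 1.33), with camera adjusted p of 0.113, 0.627 and 0.835. The endothelial list passed as higher without diseased replicate 1 (0.0165), without un-diseased replicate 2 (0.0195), with no filter beyond 1 count (0.0104) and with the block without pair 1 (0.0466), and the matrix enzyme list as lower with the block without pair 2 (0.0344). Rises and falls adjusted over the list alone numbered 1 and 3 for complement, 0 and 1 for matrix enzymes, 1 and 2 for Wnt, 1 and 2 for the unfolded protein response, and 3 and 1 for hypoxia. They numbered 4 and 1 for endothelial, 3 and 1 for pericyte and 1 and 2 for Schwann cell genes. With the block, over all genes, the 5 former lists had 4 and 3, 3 and 7, 3 and 3, 3 and 5, and 5 and 7, and the 3 latter 3 and 1, 2 and 1, and 1 and 2.

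**Figure D3:**
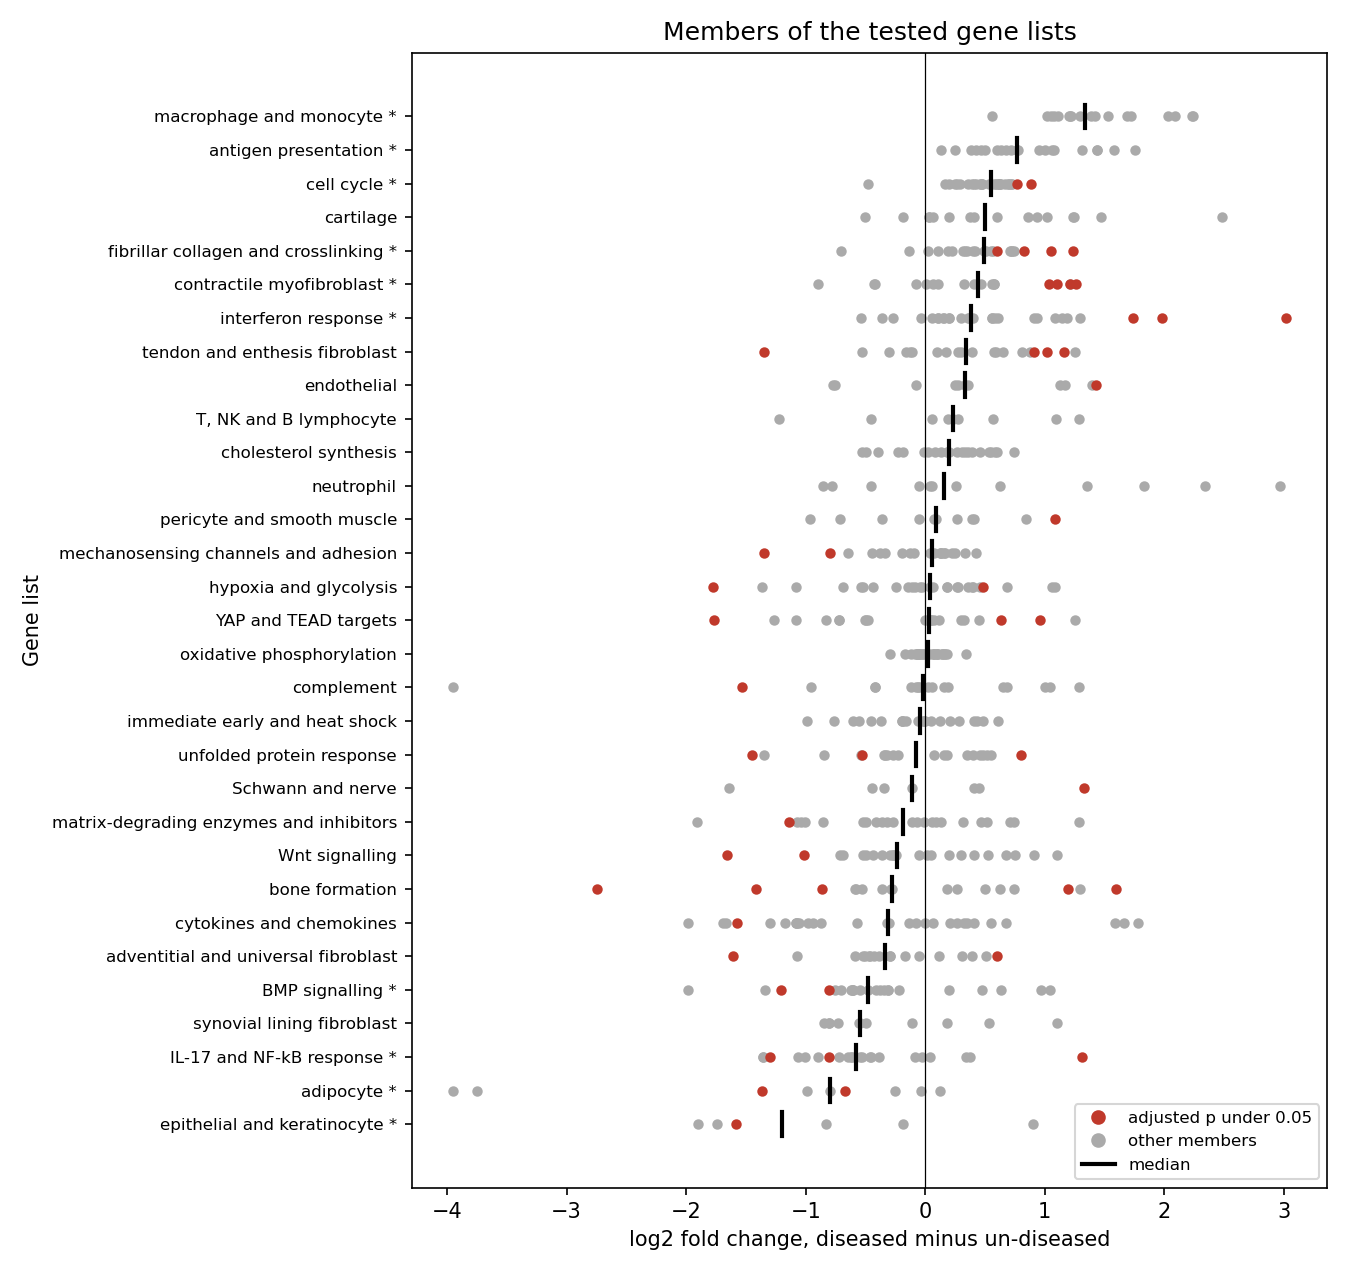
Log2 fold change, diseased minus un-diseased, of each tested member of the 31 lists, with a bar at the list median; red points had an adjusted p under 0.05 by edgeR and an asterisk marks a camera adjusted p under 0.05. The macrophage list had the highest median, 1.34, and the epithelial list the lowest, -1.20.

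In 6 other tested lists 0 members passed by edgeR: cartilage, synovial lining, cholesterol synthesis, oxidative phosphorylation, immediate early and heat shock genes, and lymphocytes. Their camera adjusted p were 0.136, 0.299, 0.371, 0.835, 0.911 and 0.688, and 5, 5, 3, 1, 5 and 1 of their members had an unadjusted p under 0.05, while DESeq2 called 2, 3, 0, 1, 4 and 0. The cartilage list passed as higher without diseased replicate 1 (adjusted p = 0.0049), without un-diseased replicate 2 (0.0279), with no filter beyond 1 count (0.0433) and with the block without pair 1 (0.000942). Without diseased replicate 1 the cholesterol list passed as higher (0.00199), as it did with the block without pair 1 (0.00774), where the synovial lining list passed as lower (0.0466). With the block 3 and 0, 1 and 4, 0 and 1, 1 and 1, 3 and 4, and 1 and 1 of their members rose and fell. Adjusted over the list alone, 1 synovial lining gene rose and 1 fell, and 0 members of the 5 other lists passed. Col11a1 of the cartilage list had 201.1 ± 53 CPM in diseased and 110.9 ± 27 in un-diseased samples, with an adjusted p of 0.0832 by edgeR, 0.0451 without un-diseased replicate 1 and 0.0218 with the block. The lubricin gene Prg4 of the synovial lining list had 16630 ± 4029 CPM in diseased and 17960 ± 5047 in un-diseased samples, a difference smaller than the spread. Fosb, an immediate early gene, had 2215 ± 173 and 2223 ± 78.8 CPM. The osteoclast, skeletal muscle and erythroid lists had 4, 4 and 2 tested members and were not tested as lists; 0 of their members passed by edgeR, 2, 0 and 0 had an unadjusted p under 0.05, and DESeq2 called 1, 0 and 0. Nfatc1 of the osteoclast list had 195.7 ± 108 CPM in diseased and 390.2 ± 90.5 in un-diseased samples, with an adjusted p of 0.152 by edgeR and 0.00519 with the block; 1 skeletal muscle gene also fell with the block.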

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

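The blocked comparisons without 1 pair, the macrophage covariate, the GC and length correction, the blocked estimated correlation and fry, and blocked DESeq2 were chosen after seeing the data. Genes higher, lower and changed at least 2-fold numbered 637, 874 and 491 with DESeq2, and 1397, 1770 and 808 with the replicate block. With the block they were 1369, 1829 and 780 after the GC and length correction, 808, 1378 and 660 in DESeq2, 1013, 1556 and 706 without pair 1, 809, 1274 and 800 without pair 2, and 426, 583 and 476 without pair 3. Upper-quartile scaling gave 417 higher, and a threshold of 0.01 left 2 higher and 2 lower, or 383 and 671 with the block. Leaving out 1 sample gave 2 to 354 higher, 3 to 721 lower and 5 to 379 changed at least 2-fold; fewer samples were tested there, and the cause was not tested further. The signs of all 495 calls were kept under each of these that tested the gene; the stricter CPM filter tested 490. RLE factors, the other filters and limma-voom moved none of these counts by over 1.5 times; the macrophage covariate gave 261, 225 and 297, but 176 upward at 2-fold against 82.

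Sdc1 passed with the replicate block at 0.59 and, with the block, at 0.53, 0.50 and 0.72 without pair 1, 2 and 3, at 0.51 after the GC and length correction and at 0.58 in DESeq2. Adjusted over all genes, it passed without the block in none of 13 settings, at 0.41 to 0.79 when 1 sample was left out. Over its 19 alternatives the adjusted p lay between 0.000699 and 0.322. Sox5 passed in none of 19, with adjusted p between 0.0503 and 0.811. Of 10 list calls 0 held with an estimated correlation (0 of 31 lists at an unadjusted p under 0.05, smallest 0.0638), 0 with the block and an estimated correlation, 1 with fry and 3 with the block and fry; fry's test of change in either direction passed for 22 lists. With the block, 8, 8 and 9 of the 10 list calls held without pair 1, 2 and 3, and 9 after the GC and length correction. Leaving out 1 sample gave 6 to 14 list calls, 6 without un-diseased replicate 1; the calls added for the tendon, cartilage, cholesterol, endothelial, adventitial and neutrophil lists are given above. The replicate block changed no other call among the lists and named genes than those of Sdc1, Lyz2, S100a9, Col11a1, Nfatc1 and the cytokine and neutrophil lists; counts of list members moved as given above. Of 57 named genes that passed, 12, 20 and 3 passed without diseased replicate 1, 2 and 3, and 52, 6 and 10 without un-diseased replicate 1, 2 and 3; 50 passed with the macrophage covariate, 51 with the block without pair 3, 52 with limma-voom and 56 each with RLE and upper-quartile factors; 57 kept their sign in each. Calls ended by limma-voom were Ifi44, Oas1a, Oas2, Duox2 and Egln3, by the covariate Thbs4, Gfpt2, Cd248, Oas2, Pfkl, Herpud1 and Pnpla2, and by the block without pair 3 Col12a1, Cd248, Itga2, Pfkl, Herpud1 and Perp. RLE factors ended that of Pdia4 and upper-quartile factors that of Pnpla2. Totals of 16720605 to 18290870 limit genes near 0.188 CPM.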

Other observations

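The tests of sequencing depth, of a lower fibroblast share, of one ratio between macrophage markers and of myeloid RNA behind the NF-kB list were chosen after the results were seen. Further genes, chosen after their values were seen, were lower in diseased samples. The hedgehog pathway gene Hhip went from 19.7 ± 0.595 to 8.39 ± 1.12 CPM (edgeR adjusted p = 0.0241), beside Gli1, while Ptch1 had a log2 fold change of -0.30 with an adjusted p of 0.14. Aldh3a1, an aldehyde dehydrogenase, went from 53.7 ± 1.69 to 15 ± 1.33 CPM (adjusted p = 0.00262), Spock2 from 71.3 ± 4.06 to 21.2 ± 2.15 (0.00313) and Apod, apolipoprotein D, from 3167 ± 340 to 1164 ± 108 (0.0247). Fmod, the collagen-binding fibromodulin, was higher, at 1200 ± 258 against 590.8 ± 71.8 CPM (0.0392).

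The first pattern was the number of genes changed. The real split of the 6 samples gave 495 calls by edgeR, and only it, 1 of 10 splits, gave as many; the highest of the other splits gave 0, with up to 2711 genes at an unadjusted p under 0.05. By DESeq2 the other splits gave up to 834 calls against 1511, the 834 from the split that sets diseased replicates 1 and 3 with un-diseased replicate 1, a structure of the samples beside the groups. Among the 4 splits that part all 3 pairs, the real one gave 3167 blocked calls and the highest other 0, with up to 102 genes at an unadjusted p under 0.05 and up to 3 DESeq2 calls; 1 of the 4 gave as many. With 10 and 4 splits no share under 0.05 can be had. Pairing by number gave 3167 calls and the highest of the other 5 pairings 997. Thus 1 of 6 gave as many, which cannot give such a share either. With the centred macrophage score in place of the block 486 genes were called, less than 0.5 times 3167. That score, fitted with a shared slope, therefore did not account for the added calls. The centred score spanned -1.4 to 1.26 in un-diseased and -0.74 to 0.65 in diseased samples. Unequal myeloid RNA that a shared slope captures poorly was not excluded.

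The second pattern was the higher level of macrophage markers in diseased samples, with medians of 1.55, 0.96 and 2.40 within pairs 1, 2 and 3. Totals within a pair differed by at most 1.04 times, which argues against depth. The adipocyte and epithelial lists had blocked medians of -0.86 and -1.2. Markers of other cells thus did not all rise, as a lower share of fibroblasts alone would require. Both falls were known when this test was chosen, and the lists had only 9 and 6 tested members. The neutrophil, endothelial, lymphocyte and pericyte lists had 0.77, 0.31, 0.21 and 0.1, and the Schwann cell list -0.05. A lower share of fibroblasts with unequal changes of the other cells was therefore not excluded. If one source of myeloid RNA were present in unequal amounts and fibroblasts expressed none of the markers, the markers would keep 1 ratio. Of 18, 15 had the common median in their 95% interval, short of the bound of 16 and above the excluding bound of 9. With an interval from the normal distribution, the form computed first, 14 did. The intervals of Cd68, Mrc1 and Cd14 lay below the common median. That median came from the same markers, and some intervals were wide, as for Fcgr1 from 0.963 to 3.602. The count therefore decides little. More macrophages in diseased samples may explain the higher markers, as may expression by the fibroblasts themselves, and the 2 cannot be told apart.

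The third pattern was the higher collagen list with a lower NF-kB list. After the trend on GC content and length was removed with the block, 97.7% or more of each median remained (98.2% of genes had a value), with camera adjusted p of 9.17e-05 and 0.000195, which argues against GC content and length as the whole cause. With the block and an estimated correlation, without that correction, the lists had adjusted p = 0.891 and 0.709, so neither list call holds there. With more myeloid RNA the NF-kB list would be raised, and its blocked median was -0.62. This leaves a myeloid contribution undecided, for the collagen list too. The test could not have come out otherwise, since a lower NF-kB list is part of the pattern. A change of state of the fibroblasts with disease may explain it, an untested hypothesis, and a different mix of fibroblast types stays open: within pairs 1, 2 and 3 the tendon list had medians of 0.39, 0.62 and 0.29, the adventitial list -0.36, -0.48 and -0.14 and the synovial lining list -0.1, -0.2 and -0.96, with blocked camera adjusted p of 0.0553, 0.0553 and 0.135.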
